A study of Arabidopsis thaliana with 3 samples.

How the data were processed

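RNA of 2-week-old pfd4 and Col-0 plants held at 4 °C for 24 h was measured on 3 arrays that each took both genotypes. Per the labels' protocols, total RNA was extracted with Trizol and purified on columns, and amplified aminoallyl RNA was coupled to Hyper5 or Cy3. The dyes were exchanged on array 3. The labels call the arrays biological replicates, and a common statement of replicate 1 on all 3 was overruled by the number in each title. Each genotype group came as the pair on an array, so the ratio within an array was the unit of the test.

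The deposited values are log2 ratios, 1 per spot and array, normalized by the authors; per the submitters' processing notes they used limma, whose version, background correction and normalization settings are not given in the sources used here. The log base is not stated either and was taken as 2 because limma writes log2 ratios. The values carry 2 decimals, and their medians over all spots were -0.01, 0.01 and 0.01 on arrays 1, 2 and 3. The labels name the dye of each genotype but not which channel was divided by which. PFD4 is negative in all 3 deposited columns, including the one with exchanged dyes, so the columns were taken as already turned the same way, to pfd4 over Col-0. If the numerator was Col-0, every direction given here turns as a whole. No signal intensities were used here, so the brightness of a spot over background is unknown and no filter on dim spots was run. The number of arrays limits the precision. Both deposited tables held the same values at all 45220 spots once spot positions were matched.

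Of the 45220 spots, 38613 carried a locus code, 5190 another transcript and 1417 were controls. Control spots and transcripts without a locus were left out of the tests. The spots of a locus were averaged per array, which gave 29030 loci, 21664 of them with 1 spot and 7366 with several, up to 13. Within loci of several spots, the spots differed with an SD of 0.36, 0.38 and 0.34 on the 3 arrays. No value was missing. Symbols came from the deposited annotation and from a RefSeq gene table of assembly TAIR10.1, in which 28595 loci were found. The genome build of the array is not given in the sources used here, so no coordinates are given.

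Each locus was tested with limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes on the mean of the 3 ratios against 0, two-sided. The p-values were adjusted by Benjamini-Hochberg over all loci, with a threshold of 0.05. The residual degrees of freedom were 2 and the prior added 2.68. Errors are SDs over the 3 arrays. The choice of test, lists, alternatives and named genes was made before the data were examined. The rule named up to 12 passing genes in each direction, or, as none passed, the 6 with the smallest p in each direction, together with PFD1 to PFD6, HY5, HYH and CBF1 to CBF3, and members that pass in a list.

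Gene lists were fixed by locus, and a member entered only where the annotation or the gene table carried its symbol. Of 288 members in 21 lists, 270 were used. Left out were PFD2, COR28, UGT75C1, 3AT1, 3AT2, HSP70-4, HSP17.6B, HSP23.6, HSP22 and the 9 CCT chaperonin genes, so the chaperonin list was not tested among them; with all members by locus it was not called (adjusted p = 0.404). The remaining 20 lists were tested with camera at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 20, with camera at an estimated correlation and fry beside it. Camera compares a list with all other loci, and fry asks whether the members of a list move one way on balance. Fry's test for a change in either direction gave an adjusted p of 0.0479 for tubulins and for prefoldin subunits, and 0.0514 for both with all members by locus. Differences between groups of genes were tested by exact permutation of the gene labels with numpy 2.4.6 and pandas 2.3.3, two-sided.

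The procedure was tested on simulated data of 29030 loci and 3 arrays, 20 times, with 200 changed loci. Limma recovered 2.3% of changes of 1 on the log2 scale, 75.6% of changes of 2, 92.2% of changes of 3 and 98.6% of changes of 5, with 7.65 false calls on average. Rank product, run with fewer draws than on the real data, gave 93.25 false calls on average. The simulated arrays were independent, while real arrays 1 and 2 correlated at 0.40 and arrays 1 and 3 at -0.27 over loci. The shares also depend on the 200 changed loci, since the Benjamini-Hochberg adjustment is stricter where fewer loci change. For both reasons these shares may not carry over, and with fewer changed loci they would be lower. In the real data MRD1 at -4.94 and PFD4 at -2.65 did not pass (adjusted p = 0.887 for both in limma). For lists whose genes were correlated at 0.3 without any shift, camera at the preset correlation called 20.8% and at the estimated correlation 0%. With a shift of 1 at that correlation they called 100% and 33.2%. No higher correlation was simulated. The estimates from the arrays were higher for some called lists, as 0.646 for salicylic acid and defence and 0.459 for abscisic acid response. For such lists 20.8% may therefore be too low a share of false calls.

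Alternatives were median centring, scale and quantile normalization between arrays, a dye term in the design, the first spot of each locus, array weights, robust eBayes, a test without moderation, other thresholds, each replicate left out in turn, the sign of array 3 turned, and camera on ranks. Turning the sign of array 3 reads every array as Cy3 over Hyper5, and so compares the dyes instead of the genotypes. Rank product and lists with all members by locus were added after the data were seen.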

Results

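Transcript levels were compared between the Arabidopsis thaliana mutant pfd4, which carries a lesion in a gene for a subunit of prefoldin, and its wild type Col-0 after a cold treatment. Prefoldin is a cytosolic chaperone complex that hands newly made actin and tubulin chains to the chaperonin for folding. Plants were 2 weeks old, grown at 22 °C in days of 16 h of light and 8 h of darkness, and were then held at 4 °C for 24 h. Hybridisations to 3 dual-dye arrays of 45220 spots form the single group, and on each of the 3 arrays pfd4 RNA competed with Col-0 RNA. On arrays 1 and 2 the pfd4 RNA carried Cy3 and the Col-0 RNA Hyper5, and on array 3 the dyes were exchanged. The number of arrays limits the precision, and no plants kept at 22 °C were compared here, so the values describe the genotypes in the cold and not the response to cold. All values are log2 ratios of pfd4 over Col-0, and this direction is called likely: the labels give the dyes but not the numerator, and it was read from the lower PFD4 transcript on every array.

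The first comparison asked how the transcript of the mutated gene stood in the mutant. The PFD4 transcript (AT1G08780) was lower in pfd4 by 6.29-fold, with log2 ratios of -3.08, -2.71 and -2.17 on the 3 arrays and a mean of -2.65 ± 0.46 (SD, n = 3). The other prefoldin subunits lay slightly above 0. PFD6, a beta-type subunit, had a mean of 0.51 ± 0.16 (SD, n = 3) and was positive on all 3 arrays. PFD3, an alpha-type subunit, had 0.43 ± 0.51, PFD1 had 0.40 ± 0.18, PFD5 had 0.31 ± 0.12 and PFD2 (AT3G22480) had 0.26 ± 0.11. Adjusted over the list alone, PFD4 (adjusted p = 0.000413) and PFD6 (adjusted p = 0.0325) passed limma's test among the 5 prefoldin members tested, and over all 29030 loci neither did (adjusted p = 0.887 for both). The list as a whole was not called by camera (adjusted p = 0.118). With PFD2 counted in, an alternative added after the data were seen, it was called up (adjusted p = 0.0449, and adjusted p = 0.568 with an estimated correlation). Over the 5 members the mean of -0.20, which holds PFD4, differed in sign from the median of 0.40 and from the direction of the test, which was up. Because the direction of the ratios was read from PFD4, its lower level is no independent check of the labels.

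The main comparison asked which transcripts differed between pfd4 and Col-0 after 24 h at 4 °C. The lower transcripts with the smallest p were AT3G01345, an expressed protein of no stated function, at -2.56 ± 0.15 (SD, n = 3), PFD4 itself, and MRD1 (AT1G53480) at -4.94 ± 1.095, a 30.8-fold lower level. They were followed by CML41, a calmodulin-like protein, at -1.98 ± 0.38, the receptor kinase gene HAE at -1.05 ± 0.06 and the expansin gene EXPA16 at -1.06 ± 0.09. Among the higher transcripts, PR1, a marker of salicylic acid responses, had the smallest p, at 1.76 ± 0.43 or 3.38-fold. It was followed by AT4G22517, annotated as a protease inhibitor, seed storage and lipid transfer family protein, at 0.97 ± 0.21, the transcription factor WRKY46 at 1.11 ± 0.33, and AT5G20190 at 0.78 ± 0.07. MYB60, a MYB transcription factor known from guard cells, had 0.73 ± 0.07 and AT4G12680 had 0.75 ± 0.10. None of these transcripts passed the threshold over all loci.

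**Figure D1:**
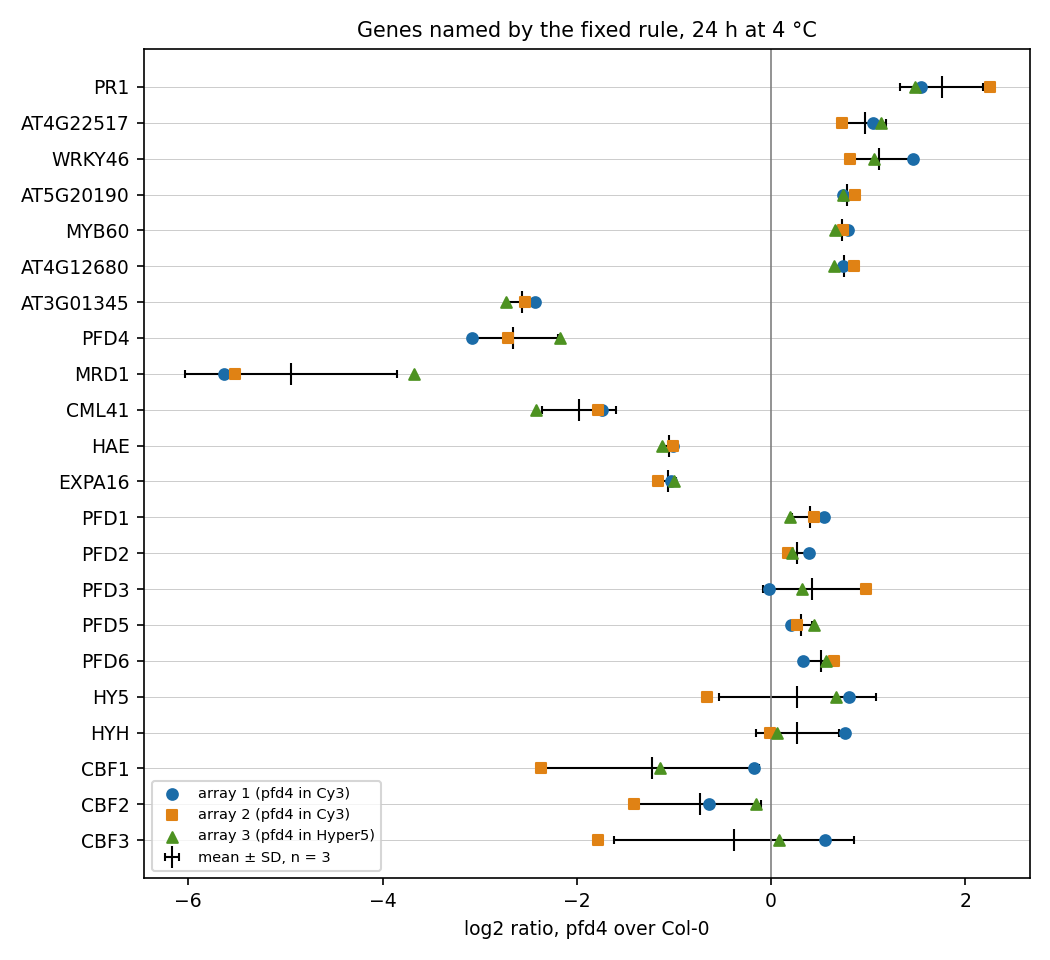
Log2 ratios of pfd4 over Col-0 (horizontal axis) for the 22 genes named by the fixed rule (vertical axis), with 1 symbol per array and the mean ± SD of the 3 arrays in black. PFD4 lies between -3.08 and -2.17 on all arrays, while CBF1 spreads from -2.37 to -0.17 and HY5 lies on both sides of 0.

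Of the 29030 loci tested with limma, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.314 (AT3G01345). At an unadjusted p under 0.05, 1372 loci remained, 622 higher and 750 lower in pfd4, where chance alone gives 1452. Rank product, a method added after the data were seen, called 34 loci, and 105 with the sign of array 3 turned. The same sign on all 3 arrays was found at 7065 loci, or 24.3%, where chance gives 25%. At least 2-fold higher on all 3 arrays were 5 loci and at least 2-fold lower 7 loci, a total of 12 where turning the sign of array 3 gives 40. This count was made with no test and its genes were named after their values were seen. The 5 were DFR, AT4G22870, AT2G16367, UGT79B1 and PR1, and the 7 were HAE, EXPA16, CAX7, CML41, AT3G01345, PFD4 and MRD1. The arrays differed from each other over loci: arrays 1 and 2 correlated with r = 0.40 (rho = 0.36), arrays 1 and 3 with r = -0.27 (rho = -0.24), and arrays 2 and 3 with r = -0.04 (rho = -0.07). These correlations are across genes, which are not independent replicates. The log2 ratios spread more widely on array 2 (SD over loci of 0.55) than on arrays 1 (0.36) and 3 (0.37).

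Regulators of light and cold responses that were named in advance did not pass either. HY5, a bZIP factor of light signalling, had log2 ratios of 0.80, -0.66 and 0.67 on the 3 arrays, so that its mean of 0.27 ± 0.81 (SD, n = 3) lay within the spread, and its homologue HYH had 0.27 ± 0.43. CBF1, CBF2 and CBF3, the factors that switch on cold-regulated genes, had means of -1.23 ± 1.103, -0.73 ± 0.64 and -0.38 ± 1.24. CBF1 and CBF2 were negative on all 3 arrays (unadjusted p = 0.0392 and 0.0432 in limma, adjusted p = 0.887 for both). Without replicate 2 their means were -0.655 and -0.395 (unadjusted p = 0.101 and 0.135 in limma). CBF3 was negative on array 2 alone and its mean without replicate 2 was 0.32.

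The last comparison asked whether groups of related genes shifted together in pfd4. Among 20 lists fixed before the data were examined, camera with a preset correlation of 0.01 called 12, of which 4 were higher and 8 were lower in pfd4. With a correlation estimated from the arrays none of the 12 was called (adjusted p = 0.518 with an estimated correlation for each of the 12), nor with fry (adjusted p from 0.594 to 0.707), and over all loci no member of any list passed. The calls below are those at the preset correlation, and rose and fell name the direction of such a call only. With the sign of array 1 or of array 2 turned, that test still called 8 and 9 lists.

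Anthocyanin and flavonoid enzymes rose as a list (mean log2 ratio 0.64, median 0.33, adjusted p = 0.00241, and adjusted p = 0.518 with an estimated correlation). With all 18 fixed members, an alternative added after the data were seen, the median was 1.04 (adjusted p = 0.00012, and adjusted p = 0.568 with an estimated correlation). The median on array 2 was then 1.24, against -0.26 over the 15 members tested. Of the 15 members tested, 6 passed when adjusted over the list alone and 0 over all genes, and all 6 were higher, while of the 18 members 10 passed over that list. They were DFR and LDOX, which make leucoanthocyanidins and anthocyanidins, the glycosyltransferase gene UGT79B1, the malonyltransferase gene 5MAT, F3'H, which hydroxylates the B ring, and TT19, a glutathione transferase needed for vacuolar transport. DFR had log2 ratios of 1.13, 4.32 and 2.07 on the 3 arrays (2.51 ± 1.64, SD, n = 3, adjusted p = 0.0358 over the list). LDOX had 1.93 ± 1.26, UGT79B1 1.81 ± 0.85, 5MAT 1.32 ± 0.84, F3'H 1.303 ± 0.62 and TT19 1.07 ± 0.68, all positive on 3 of 3 arrays. Chalcone synthase, CHS, which opens the pathway, had 0.22, -0.94 and 0.25, and F3H had 0.40, -1.41 and 0.60. Without replicate 3 the list was no longer called (adjusted p = 0.176), nor on ranks (adjusted p = 0.0688). LDOX and AT4G22870 carry similar sequences, and hybridisation between them cannot be excluded.

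Flavonoid regulators were not called (adjusted p = 0.136), and 0 of 12 members passed over the list alone or over all genes. The MYB activators of anthocyanin genes PAP1 and PAP2 had means of 1.05 ± 0.86 and 1.21 ± 0.90 (SD, n = 3), both positive on all 3 arrays. MYBL2, a repressor of the pathway, had -0.35 ± 0.76.

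Tubulins fell as a list (mean -0.28, median -0.34, adjusted p = 0.000657, and adjusted p = 0.518 with an estimated correlation). Of 15 members, 8 were negative and 3 positive on all 3 arrays, and the 3 positive were the alpha-tubulin genes TUA2 (0.51 ± 0.24, SD, n = 3), TUA4 (0.15 ± 0.12) and TUA6 (0.55 ± 0.36). TUB6 alone passed when adjusted over the list alone (-0.79 ± 0.13, adjusted p = 0.0304), and 0 members over all genes. The 9 beta-tubulin genes all had negative means, from -0.81 in TUB7 to -0.26 in TUB5. Tubulin genes share sequence, so a spot can also take up the transcript of a relative. Without replicate 1 the mean was -0.17 and the call was lost (adjusted p = 0.0504). Actins fell by the same test (mean -0.17, adjusted p = 0.0463, and adjusted p = 0.518 with an estimated correlation), with 0 of 8 members passing over the list alone or over all genes and ACT8 at -0.52 ± 0.33. That call was lost without any of the 3 replicates in turn (adjusted p from 0.0594 to 0.301), with array weights (0.0771), on ranks (0.0574) and with the first spot of each locus (0.132).

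**Figure D2:**
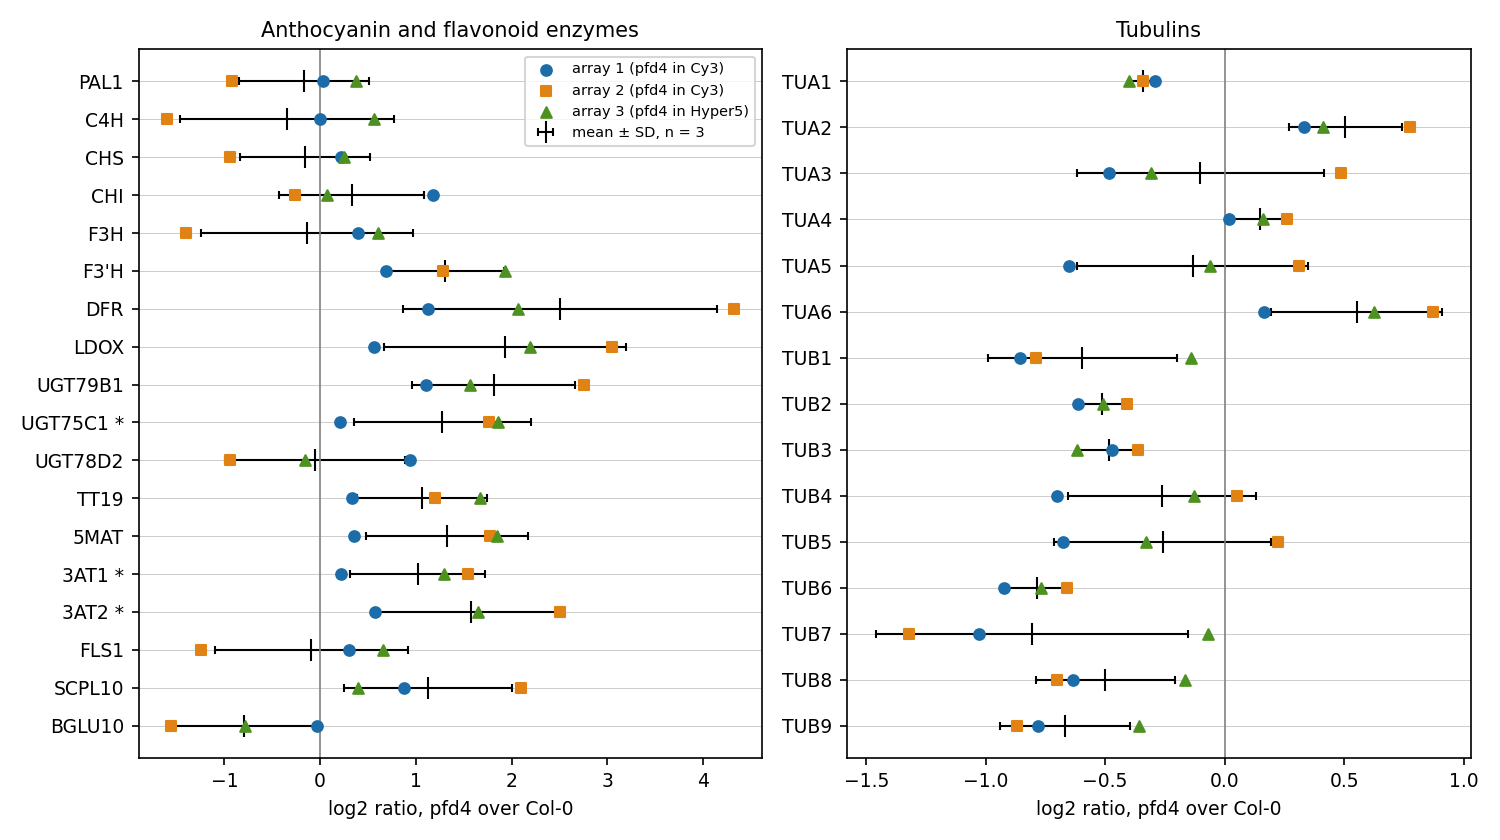
Log2 ratios of pfd4 over Col-0 (horizontal axes) for each anthocyanin and flavonoid enzyme (left) and each tubulin (right), with 1 symbol per array and the mean ± SD of the 3 arrays in black. Members with an asterisk were plotted but kept out of the list test because the sources did not carry the symbol for the locus. DFR reaches 4.32 on array 2 and 1.13 on array 1, and the beta-tubulins lie mostly below 0.

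Salicylic acid and defence genes rose as a list (mean 0.50, median 0.42, adjusted p = 0.000707, and adjusted p = 0.518 with an estimated correlation). PR1 alone passed when adjusted over the list alone, of 16 members, and 0 passed over all genes. WRKY70 had 0.42, 2.27 and 1.00 on the 3 arrays, and the isochorismate synthase gene ICS1, which makes the precursor of salicylic acid, had 0.97, 1.505 and 0.05. The list's median was 1.06 on array 2 and -0.06 on array 3, and without replicate 2 the mean was 0.18 and the call was lost (adjusted p = 0.101). The list was also called with every array read as Cy3 over Hyper5 (mean 0.494, adjusted p = 0.000827 in camera). With a dye term in the design the mean was 0.38 and the call was kept (adjusted p = 0.0069 in camera). An effect of dye, or one shared by arrays 1 and 2, therefore stays open for this call. LSM proteins, which form rings that bind RNA in splicing and decay, also rose (mean 0.28, adjusted p = 0.000707, and adjusted p = 0.518 with an estimated correlation). No LSM gene passed over the list alone or over all genes, 6 of 11 were positive on all 3 arrays, LSM8 had 0.57 ± 0.38 (SD, n = 3), and the call was lost without replicate 3 (adjusted p = 0.12). Cell wall expansion genes rose (mean 0.31, adjusted p = 0.0175, and adjusted p = 0.518 with an estimated correlation), and EXPA1 at 1.01 ± 0.39 and XTH31 at 0.73 ± 0.12 were the 2 of 18 that passed over the list alone, with 0 over all genes. That call was lost without replicate 3 (adjusted p = 0.37), with array weights (0.0577) and on ranks (0.0688).

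The CBF pathway and cold-regulated genes fell as a list (mean -0.42, median -0.47, adjusted p = 0.00163, and adjusted p = 0.518 with an estimated correlation), with 0 of 21 members passing over the list alone or over all genes. The arrays differed: the list's median was 0.42 on array 1, -1.29 on array 2 and -0.66 on array 3. The galactinol synthase gene GOLS3 had -0.59, -3.42 and -0.70, and COR15A, which encodes a chloroplast protein that protects membranes from freezing, had 2.19, 1.37 and -1.36. Abscisic acid response genes fell (mean -0.45, adjusted p = 0.00103, and adjusted p = 0.518 with an estimated correlation), with 0 of 20 passing over the list alone or over all genes and medians of 0.35, -0.73 and -0.62 on the 3 arrays. NCED3, an enzyme of abscisic acid synthesis, was negative on all 3 arrays (-1.29 ± 1.00, SD, n = 3). Both calls were lost without replicate 2 (means of -0.12 and -0.19, adjusted p = 0.0594 for each) and without replicate 3 (adjusted p = 0.301 and 0.333). Without replicate 1 the means were -0.79 (adjusted p = 2.66e-08) and -0.86 (adjusted p = 2.35e-12). These p-values rest on 2 arrays and on the preset correlation. The correlations estimated from all 3 arrays were 0.396 and 0.459, so these p-values are too small.

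Jasmonate genes fell (mean -0.34, adjusted p = 0.00089, and adjusted p = 0.518 with an estimated correlation), with 0 of 15 passing over the list alone or over all genes, LOX2 at -0.66 ± 0.43 (SD, n = 3) and VSP1 at -0.50 ± 0.26. Gibberellin genes fell (mean -0.33, adjusted p = 0.0186, and adjusted p = 0.518 with an estimated correlation), with 0 of 9 passing over the list alone or over all genes and GA3OX1, the enzyme of the last step to active hormone, at -0.95 ± 0.64. Heat shock proteins and cytosolic chaperones fell (mean -0.43, adjusted p = 0.0146, and adjusted p = 0.518 with an estimated correlation), with 0 of 11 passing over the list alone or over all genes. Their median was -1.17 on array 2 against -0.06 on array 1 and -0.29 on array 3, and over all 15 fixed members it was -0.34 on array 2. Jasmonate genes had medians of 0.05, -0.62 and -0.30 on the 3 arrays, and gibberellin genes -0.14, -0.67 and 0.04. Without replicate 2 the mean was -0.17 for jasmonate (adjusted p = 0.0594), -0.07 for gibberellin (adjusted p = 0.581) and -0.13 for heat shock genes (adjusted p = 0.0888), and all 3 calls were lost. The gibberellin call was also lost without replicate 3 (adjusted p = 0.0815) and on ranks (0.0521).

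Lists of markers for other organs and stages were included because whole plants can differ in their make-up. Floral organ markers fell slightly (mean -0.18, adjusted p = 0.0186, and adjusted p = 0.518 with an estimated correlation), with 0 of 7 passing over the list alone or over all genes and AP1, a floral meristem gene, at -0.64, -0.58 and -0.09. That call was lost without replicate 1 (adjusted p = 0.0636) and without replicate 2 (mean -0.11, adjusted p = 0.154), and with a dye term in the design (mean -0.14, adjusted p = 0.0517). Root markers (adjusted p = 0.736) and leaf senescence markers (adjusted p = 0.447) were not called, although the sugar transporter gene SWEET15 passed when adjusted over the list alone (0.81 ± 0.21, SD, n = 3, adjusted p = 0.0132) and not over all genes. Glucosinolate synthesis (adjusted p = 0.093), photosynthesis (adjusted p = 0.118), circadian clock (adjusted p = 0.36) and light signalling (adjusted p = 0.74) were not called, and no member of these lists passed over the list alone or over all genes.

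**Figure D3:**
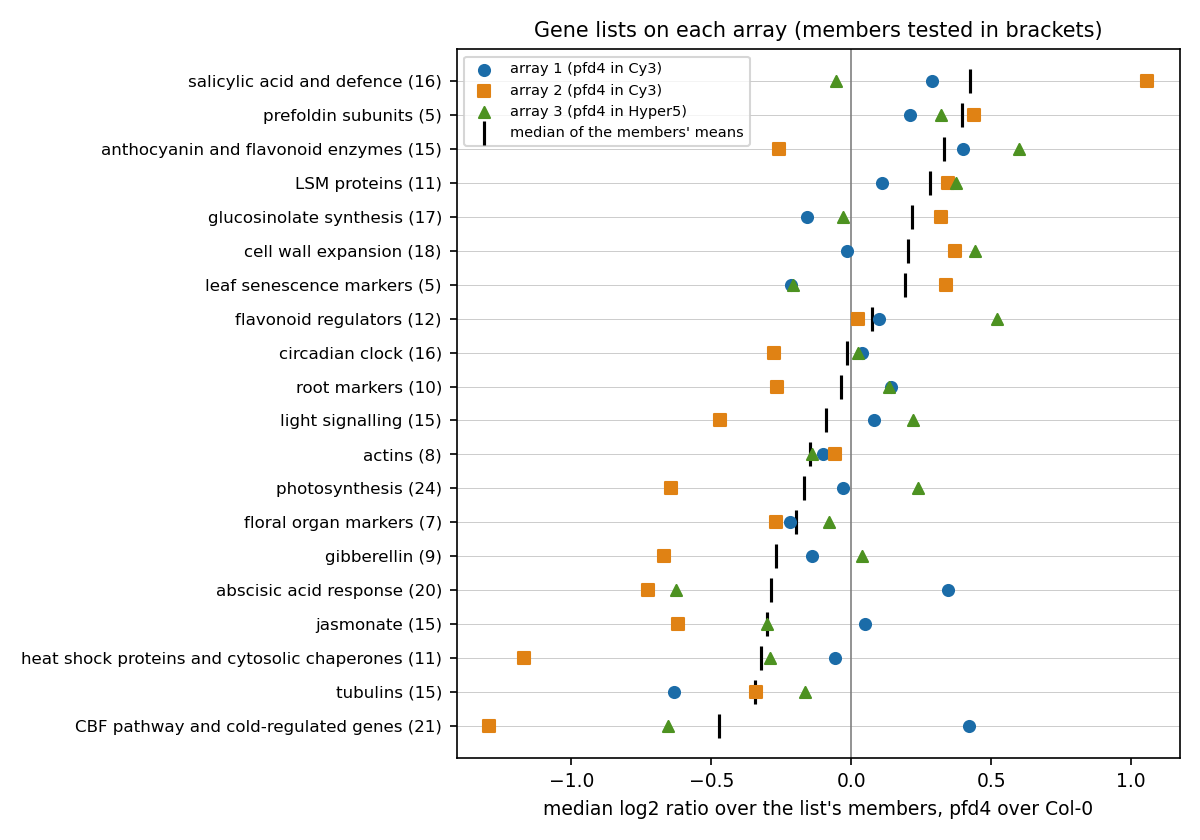
Median log2 ratio of pfd4 over Col-0 over the members of each list (horizontal axis) for the 20 lists tested (vertical axis, members tested in brackets), with 1 symbol per array and the median of the members' means as a black bar. The CBF list lies at 0.42 on array 1 and at -1.29 on array 2, and the tubulins lie below 0 on all 3 arrays.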

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

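In this part, only limma with a dye term was listed in advance, and all other tests were chosen after the pattern they address was seen. The prediction for a local defect on array 2 was written before the result of that test, and the other predictions after.

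Outside the loci tested, 2 of the 5190 spots for other transcripts were at least 2-fold off on all 3 arrays, against 0 of 757 dark and negative control spots and 15 of 38613 locus spots. The control spots are too few to show a difference from 2 in 5190. The transcript CD533642, annotated as a dihydroflavonol 4-reductase of Arabidopsis thaliana, had a mean log2 ratio of 1.87, in the direction of DFR. DFR encodes that enzyme, so the spot may measure DFR itself and is no independent support. The transcript BX819228 had -1.293.

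The arrays with opposite dyes went apart: array 3 correlated with array 1 at r = -0.27 over loci. A wrongly turned sign of array 3 is argued against by PFD4 alone, which as deposited lay at -2.17 on array 3, below 0 as on arrays 1 and 2. The direction of the ratios was read from these same PFD4 values, so this is no separate check. A dye bias of single genes could account for part of it, but in the dye orientation the lower of the correlations of array 3 with the other arrays was 0.035, close to 0, so it stays open. In limma with a dye term, 0 loci passed for the genotype, and over loci the dye coefficient spread more widely (SD 0.29) than the genotype coefficient (SD 0.25). No biological explanation was tested, since each array compares the same genotypes.

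A set of 7 heat shock genes was far lower on array 2 than on the other arrays. They were HSC70-1, AT3G12580, HSP90.1, HSP101, HSP17.6A, HSP17.6II and HSFA2, with a median of -1.86 on array 2, 0.04 on array 1 and -0.46 on array 3, and AT3G12580, an HSP70 gene, reached -5.29. A local defect of the array is argued against by the spots around their 15 spots, whose median log2 ratio on array 2 was 0.07. These 7 were picked from 15 list members for being at least 2-fold lower there, and the other 8 lay between -0.34 and 0.31 on array 2. The wider range of array 2 therefore stays open, although scaled to the spread of the other arrays the median of the 7 was -1.24. A stress that reached 1 genotype's plants of that replicate may account for it, and ratios do not show which genotype moved. For these 7 genes, a genotype effect as large in every replicate as on array 2 is argued against by their medians on arrays 1 and 3. Because the 7 were picked for low values on array 2, a smaller effect of equal size in every replicate is not excluded. A smaller genotype effect, or one that varied between replicates, cannot be told apart from such a stress.

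Late anthocyanin genes had higher log2 ratios than early flavonoid genes, with means of 1.29 over 10 genes and 0.09 over 8 genes. The exact permutation p was 0.00432, two-sided (Benjamini-Hochberg p = 0.00432 over 2 such comparisons). With UGT78D2 counted as late, the exact permutation p was 0.016. Late genes were DFR, LDOX, UGT79B1, UGT75C1, TT19, 5MAT, 3AT1, 3AT2, SCPL10 and BGLU10. Among them UGT75C1, 3AT1 and 3AT2 had been left out of the list test by the rule on symbols. Counted as early were the other list members, PAL1, C4H, CHS, CHI, F3H, F3'H, UGT78D2 and FLS1. Against the pattern, late BGLU10 was negative on all 3 arrays (mean -0.79) and early F3'H positive on all 3 (mean 1.303). A dye bias is argued against, since the late genes' median was 1.66 on array 3, where the dyes were exchanged, and 0.46 and 1.94 on arrays 1 and 2. The early genes' medians were 0.35, -0.94 and 0.47, and late minus early was 0.06, 2.70 and 0.84 on arrays 1, 2 and 3, so array 1 showed almost no difference. Whether array 2 alone carries it stays open: without it the difference was 0.45 instead of 1.201 (exact permutation p = 0.0642). That late and early genes may respond differently in pfd4 is a hypothesis. Genes of a pathway are not independent, so the permutation p is too small. With the array as the unit, the smallest p an exact sign-flip test of 3 arrays can give is 0.25.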

How the results depend on the processing

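In this part, rank product and lists of all members by locus were chosen after the data were seen. The count of 0 loci in limma was 0 in every alternative listed in advance that was run, including thresholds of 0.01 and 0.1, and rank product called 34, which in simulated data made many false calls; the cause was not tested. PFD4 was negative in every alternative, from -2.90 to -2.44 with 1 replicate left out and -1.21 with the sign of array 3 turned. With limma, none of the 21 further named genes passed in any setting, so only their direction could change, and 229 of 231 alternatives kept it. Rank product called MRD1, PR1, AT3G01345 and CML41 of them (adjusted p = 0.00182 each). Some of these lay near 0, as HY5 (0.005) and HYH (0.027) without replicate 1. The exceptions were CBF3, at 0.32 without replicate 2 (from -0.85 to 0.32 with 1 replicate left out), and HY5 at -0.18 with the sign of array 3 turned.

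The count of 12 lists fell to 0 with an estimated correlation and to 0 with fry, to 2 with the sign of array 3 turned, and lay between 6 and 10 with 1 replicate left out. It was 13 with all members by locus. Salicylic acid and defence alone of the 12 kept its call with the sign of array 3 turned (adjusted p = 0.000827 in camera). With the sign of array 3 turned, the direction of the test reversed for LSM proteins (mean 0.041), the CBF list (-0.048), anthocyanin enzymes (0.054), abscisic acid (0.053) and cell wall genes (0.051), with adjusted p from 0.672 to 0.931, so none was called the other way, and only the abscisic acid mean changed sign; the cause was not tested. Of 168 alternatives of the 12 lists, 107 kept the call, 56 lost it and 5 reversed. The main test was itself paired, since it used the ratio of pfd4 to Col-0 within each array. With 1 group, no further pairing was possible. Not run were the other deposited table, whose values are identical, the filter on low signal and the trend, for which no signal was used here, and values on at least 2 arrays, as none was missing. Scale, quantile and median centring kept the calls of all 12 lists.

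With 3 arrays there are 4 ways of turning their signs, too few for a share under 0.05. All 4 gave as many limma calls as the real signs (0, highest other 0), and 1 of 4, the real one, gave as many lists (12, highest other 9). With array 3 turned, which reads every array as Cy3 over Hyper5, 3878 loci had an unadjusted p under 0.05 in limma against 1372. More loci thus held across the arrays by dye than by genotype. A dye bias cannot be told apart here from a feature that arrays 1 and 2 share, so the source stays open.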

Other observations

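In this part, all tests were chosen after the values were seen, and the gene groups of the next paragraph were not fixed in advance.

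Cytosolic ribosomal protein genes were higher in pfd4 as a group. Over 199 genes the mean log2 ratio was 0.23, 54 were positive and 4 negative on all 3 arrays, and the medians were 0.03, 0.35 and 0.26 on the 3 arrays. Camera gave an adjusted p of 2.28e-11 over 6 such groups, and an adjusted p of 0.571 with an estimated correlation. The 66 chloroplast genome loci had medians of 0.72 on array 1, -0.23 on array 2 and -0.07 on array 3 and were not called (adjusted p = 0.144). Mitochondrial genome loci (adjusted p = 0.144), WRKY factors (adjusted p = 0.223), histones (adjusted p = 0.223) and 1237 transposable element genes (adjusted p = 0.241) were not called.

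Beta-tubulin genes had lower log2 ratios than alpha-tubulin genes, with means of -0.54 over 9 genes and 0.10 over 6 genes (exact permutation p = 0.000599, two-sided, Benjamini-Hochberg p = 0.0012 over 2 such comparisons). The exact permutation p lay between 0.0002 and 0.0012 with 1 array left out. The beta genes' median was negative on arrays of both dye orientations (-0.70, -0.66 and -0.33). Tubulin genes share sequence and arrays and are not independent, so this p is too small. With the array as the unit, the smallest p an exact sign-flip test of 3 arrays can give is 0.25. That the families may respond differently in pfd4 stays an open hypothesis.

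MYB60 lies 3 tested loci from PFD4. A hypothesis is that the lesion may alter neighbouring loci: the median absolute log2 ratio of the 20 nearest loci was 0.25, at percentile 98.7 of 10000 random windows (median 0.13). MYB60, which prompted the test, is itself 1 of the 20. The random windows came from all tested nuclear loci and were not matched for signal, so the percentile may reflect that instead of the lesion. Of the 20, 5 had the same sign on all 3 arrays, which is what chance gives (25%). Among the 5 were the nearest tested loci on one side, AT1G08790 (mean 0.35), AT1G08800 (-0.36) and MYB60 (0.73). The nearest on the other side, PRA1.E, AT1G08760 and AT1G08750, had mixed signs. The hypothesis stays open.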
